A study of Drosophila melanogaster with 21 samples.

How the data were processed

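RNA from class IV dendritic arborization neurons, sensory neurons that tile the larval body wall of Drosophila, was measured on 21 one-colour Agilent arrays, 15 from wild type and 6 from ret mutant larvae. Per the labels' protocols, the neurons carried a red fluorescent membrane marker under the ppk promoter and were isolated by fluorescence-activated sorting, and the RNA was amplified and coupled to Cy3. Groups were taken from the genotype each label states. The labels call the replicates independent but do not say which animals or sorts they came from, so p-values measure the spread between these samples.

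The deposited scanner tables hold spot intensity on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1, which also gave each spot a processed intensity and flags for outliers, saturation and signal well above background. A deposited table of the whole series holds log2 values, and the submitters' processing notes name limma, without a version. On each array the ranks of that table equalled those of the uncorrected median intensity, with a rank correlation of 1 across probes, and its column medians lay between 7.07 and 7.08. At equal ranks its columns differed from their mean by a median of 0.000839 and at most 0.0847 on the log2 scale. Such near-equal distributions are what quantile normalization gives, a reading from the values, since no header or label used here states the step.

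Each array held 61657 non-control probes, each spotted once. The probes carry IDs, and the files do not pair them with gene names, nor could the gene table at hand be joined to the IDs. Every test was therefore made per probe. The planned level of the Ret transcript, the planned gene lists and cell type markers and the choice of 1 probe per gene were not analysed here, and no check of the genotype by the mutated gene was made.

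The processed intensity of each array was divided by its 75th percentile over non-control probes, a floor was set and log2 was taken. The floor, 0.0447 of the 75th percentile or -4.48 on the log2 scale, is the highest of the arrays' detection limits, where a limit is the lowest scaled signal among probes well above background. The floor was chosen after the data were examined. Spots with an outlier flag, between 3 and 186 per array, were left out, and no spot was saturated. Probes well above background on at least 0.5 of the arrays of 1 genotype were tested, which kept 41050 and left out 20607.

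Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Wild type arrays of the 2 slides that hold them were compared in the same way. Signal and detection per array were compared by exact two-sided permutation over all regroupings. The rule fixed before the data were examined named the highest and lowest log2 fold changes among probes past the threshold in the comparison with all arrays and, in the same direction, against the wild type arrays of each slide alone. Because probes have no gene names, 2 probes per direction are named in place of 12.

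Arrays lay on 3 slides, scanned once each. Slide 1 held the 6 ret mutant arrays, slide 2 held 7 wild type arrays and slide 3 held 8. No slide held both genotypes, so slide could not be a fixed covariate. It was fitted as a random block and each wild type slide was also used alone, but neither separates genotype from slide. The arrays' 75th percentile of signal ranged from 525.7 to 1698 and the share of probes well above background from 53.3% to 74.7%. The number of arrays limits the precision. No 2 arrays held identical values. The most similar, wild type replicates 5 and 6, had a typical log2 difference of 0.301 at bright probes and were counted as separate samples.

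The fit was tested on simulated data with the measured probe means and spreads, in the comparison of 6 ret mutant with 15 wild type arrays over 41050 probes. It recovered 17 of 80 probes changed by 1 on the log2 scale, 53 of 80 changed by 2 and 40 of 40 changed by 3, with 9 false calls. The simulated noise was normal and independent between probes and arrays, with the same spread in both genotypes. It held no slide difference, no subgroups of arrays and no floor, so these counts need not hold for the measured data.

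Alternatives covered normalization, background correction, the filter, thresholds, variance models, array weights, slide, replicate number and leaving out each array. The planned background correction uses a mean intensity; the files used here give the median, so normexp was run on the median intensity and median background with an offset of 50. Leaving out wild type replicates 1 to 3, 4 to 6 or 1 to 6, and a lower floor of 0.0122, were added after the data were examined.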

Results

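Gene expression was profiled in sorted class IV dendritic arborization neurons of wild type and ret mutant Drosophila larvae. Ret is a receptor tyrosine kinase, and the series title concerns its part, with the TGF-beta ligand maverick, in the growth of the dendrites of these neurons. The comparison asks which transcripts differ in level between neurons with and without normal ret. It covers 15 wild type and 6 ret mutant arrays. Results are given per probe, identified by the ID in the files, and the level of the Ret transcript was not analysed here.

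A large part of the array was detected in wild type neurons. Of 61657 probes, 26503 (43.0%) were well above background on all 15 wild type arrays, and 7680 (12.5%) on none of them. On all 21 arrays 25743 probes (41.8%) were detected. Detection did not part the genotypes completely: 0 probes were detected on all 6 ret mutant and no wild type arrays, and 1 on all 15 wild type and no ret mutant arrays. Partial differences in detection are not counted here. The highest counts among 99 random splits of the arrays into 6 and 15 were 2 and 1.

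Ret mutant arrays did not differ detectably from wild type arrays in overall signal. The log2 of the 75th percentile was 9.84 ± 0.32 (SD, n = 6) in ret mutant and 10.14 ± 0.44 (SD, n = 15) in wild type arrays (exact two-sided permutation p = 0.141). The share of probes well above background was 62.4% ± 6.5 (SD, n = 6) and 64.4% ± 5.58 (SD, n = 15), respectively (exact two-sided permutation p = 0.49).

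Wild type arrays, which lay on 2 slides, were more varied than ret mutant arrays, which lay on 1. The median SD of a tested probe was 0.73 on the log2 scale in wild type and 0.50 in ret mutant arrays. Across probes, which are not independent replicates, the median correlation was 0.903 for the 105 wild type pairs, 0.953 for the 15 ret mutant pairs and 0.917 for the 90 pairs across genotypes. Wild type replicates 1, 2 and 3 stood apart: they correlated at 0.911 to 0.957 with each other and at 0.798 to 0.899 with the other 18 arrays. Of the 15 wild type arrays, 11 had a higher median correlation with the ret mutant arrays than with the other wild type arrays.

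**Figure D1:**
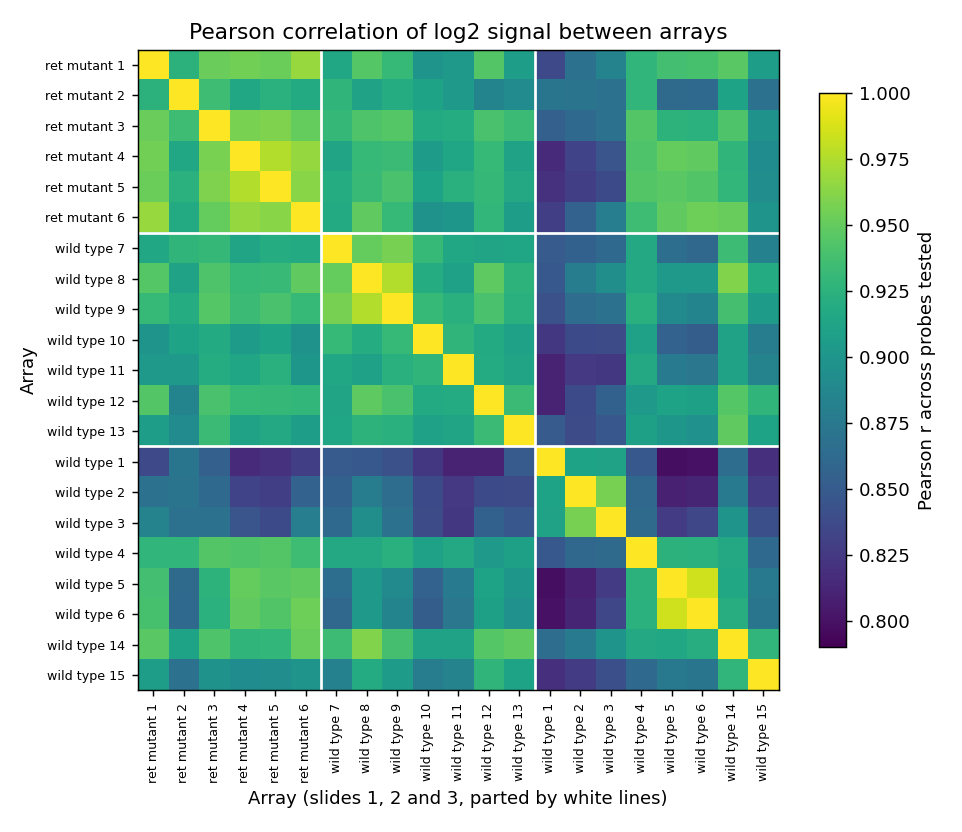
Pearson correlation of log2 signal across the probes tested, for each pair of the 21 arrays, ordered by slide, with colour giving r. Wild type replicates 1, 2 and 3 correlate at 0.798 to 0.899 with the other 18 arrays.

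Between genotypes, 74 probes were higher and 46 lower in ret mutant neurons, 120 of the 41050 tested or 0.292% (limma, adjusted p under 0.05). The median log2 fold change was 1.74 among the higher probes and -2.03 among the lower ones, and 113 of the 120 changed at least 2-fold. The higher probes ranged from 0.75 to 5.21 and the lower ones from -5.27 to -0.88. At an unadjusted p under 0.05, 2648 probes were higher and 2038 lower, 11.4% of those tested. Chance alone gives a share of about 0.05. Against the wild type arrays of each slide alone, 24 of the higher and 8 of the lower probes passed in the same direction both times. The groups did not overlap at 41 tested probes, of which 28 passed the adjusted threshold; chance gives 0.00369% of probes, or 1.51.

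The probe fv00648 was the highest by the naming rule, with a log2 fold change of 3.84 (SE 0.44, limma adjusted p = 0.00014). Its signal was -0.57 ± 1.79 (SD, n = 6) in ret mutant arrays and -4.41 ± 0.28 (SD, n = 15) in wild type arrays, on the log2 scale relative to the 75th percentile. It was above every wild type array in 6 of 6 ret mutant arrays, and 14 of the 15 wild type arrays lay at the floor, so its fold change depends on where the floor lies: it was 5.18 with the lower floor and 3.32 with normexp background correction. The probe fv00656 had a log2 fold change of 3.83 (SE 0.48, limma adjusted p = 0.0003), again with 6 of 6 ret mutant arrays above every wild type array and with 9 wild type arrays at the floor. It was 4.52 with the lower floor and 3.17 with normexp background correction. Its signal was -0.41 ± 1.75 (SD, n = 6) in ret mutant arrays and -4.24 ± 0.62 (SD, n = 15) in wild type arrays. Ret mutant replicate 2 was the highest for fv00648 and fv00656, at 2.695 and 2.832, and the next highest array was at -0.199 and -0.15. Without replicate 2 the log2 fold changes were 3.19 and 3.18. The 2 probes varied together among the ret mutant arrays, so they are not 2 independent results: Pearson's r was 0.999 (n = 6, exact two-sided permutation p = 0.00139, adjusted over 2 pairs 0.00278) and Spearman's rho was 1 (exact p = 0.00278, adjusted 0.00556). Without the 2 arrays farthest from the median r was 0.995. At both probes the ret mutant arrays varied more than the wild type arrays, and the fit takes 1 spread for both genotypes. As the wild type arrays are more numerous, the SE and adjusted p given here are too small.

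The lowest were fu04607, with a log2 fold change of -4.06 (SE 0.54, limma adjusted p = 0.00044), and fu04874, with -3.94 (SE 0.54, limma adjusted p = 0.00063). Signal of fu04607 was -2.41 ± 2.01 (SD, n = 6) in ret mutant and 1.65 ± 0.66 (SD, n = 15) in wild type arrays, and signal of fu04874 was -2.17 ± 1.99 (SD, n = 6) and 1.77 ± 0.66 (SD, n = 15). For both probes 5 of 6 ret mutant arrays lay below every wild type array. The exception was ret mutant replicate 3, at 0.80 for fu04607 and 0.88 for fu04874. Among the ret mutant arrays these 2 probes had a Pearson's r of 0.843 (n = 6, exact two-sided permutation p = 0.0347, adjusted 0.0347) and a Spearman's rho of 0.6 (exact p = 0.242, adjusted 0.242). Without the 2 arrays farthest from the median r was -0.35, so the relation rests on those arrays. Spread among the ret mutant arrays exceeded that among wild type arrays at these probes, so here too the SE and adjusted p are too small.

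**Figure D2:**
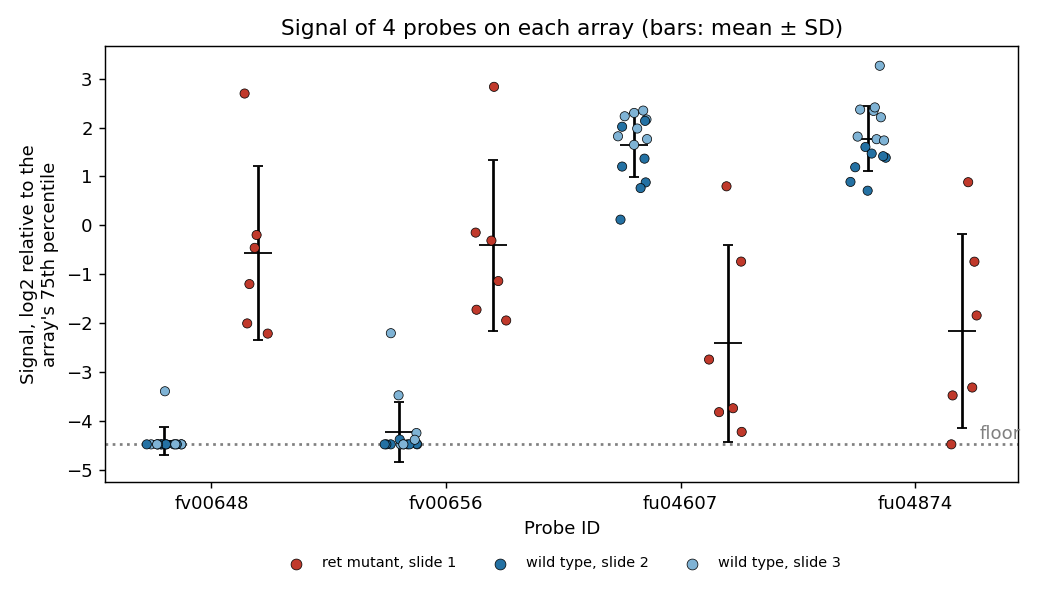
Log2 signal relative to each array's 75th percentile for 4 probes, with 1 point per array coloured by slide, bars for mean ± SD and a dotted line for the floor. For fv00648 and fv00656, 6 of 6 ret mutant arrays lie above every wild type array; for fu04607 and fu04874, 5 of 6 lie below.

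Probes with consecutive IDs often moved together. Of 115 probes past the threshold with a tested consecutive ID, 73 (63.5%) had such a neighbour changed in the same direction at an unadjusted p under 0.05, against 12.9% over all tested probes. Counted as runs of consecutive IDs, the 120 probes form 99 runs, 59 higher and 40 lower. Probes are thus not independent genes. The IDs fall into 6 classes by their first letters, whose meaning the files do not give. Between 0.259% and 0.481% of the tested probes of each class passed the threshold, with 37 higher and 23 lower among the 21873 tested probes of the most numerous class.

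The number of probes past the threshold depended on the arrays used, their weights and slide. With slide as a random block 16 probes were higher and 6 lower; against the 7 wild type arrays of slide 2 alone the counts were 512 and 654, and against the 8 of slide 3 alone 51 and 34. Without wild type replicates 4 to 6 they were 568 and 655, and with normexp background correction 70 and 25. Array weights gave 1486 and 1182, and leaving out ret mutant replicate 1, 2, 4, 5 or 6 gave 52, 61, 45, 46 or 55 probes in all. Leaving out ret mutant replicate 3 gave 129.

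**Figure D3:**
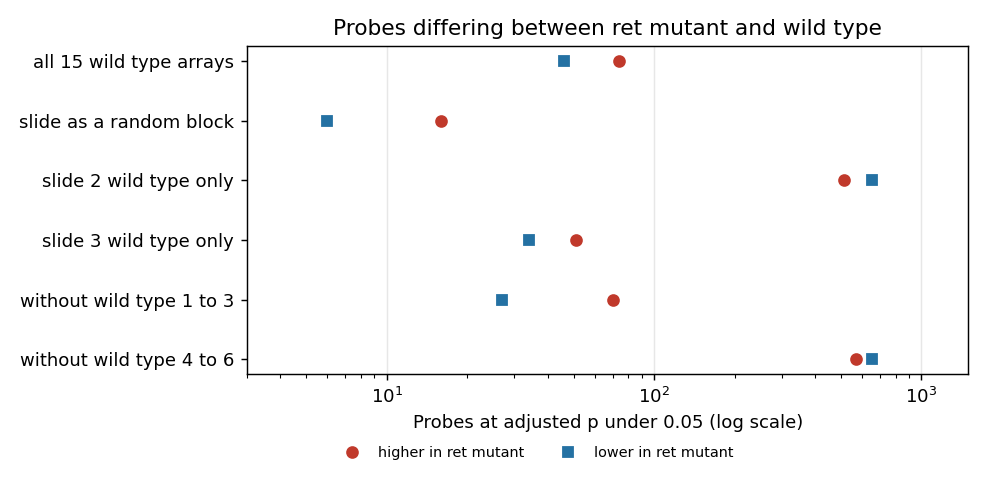
Number of probes at adjusted p under 0.05, on a log axis, higher (circles) and lower (squares) in ret mutant neurons, for different treatments of slide and of the wild type arrays. Among the treatments plotted, the counts run from 16 and 6 with slide as a random block to 568 and 655 without wild type replicates 4 to 6.

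Wild type neurons on the 2 slides were compared to show how many probes differ without a difference in genotype. Between the 8 wild type arrays of slide 3 and the 7 of slide 2, 159 probes passed the threshold, 90 higher and 69 lower on slide 3 (limma). The 120 between genotypes come from other group sizes, and with no filter on dim probes the counts were 42 between slides and 70 between genotypes. At an unadjusted p under 0.05 (limma), 7934 probes differed between the slides, more than the 2648 higher and 2038 lower between genotypes. The median absolute log2 difference of the 159 probes was 1.66. No probe was on both lists, where independent lists of these sizes would share 0.465. Without wild type replicates 1 to 3 the comparison gave 2 probes, and without replicates 4 to 6 it gave 4078.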

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

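The 9 measures examined for a ret mutant array far from the other 5 gave 4 such cases, where chance alone gives about 1 in 20. Ret mutant replicate 1 had 74.7% of probes well above background, against 56.2% to 62.8% on the other ret mutant arrays. The same array detected 67.7% of its 350 E1A control spots, against 7.71% to 20% on the other ret mutant arrays and 3.14% to 35.1% on wild type arrays. It also detected 30.2% of its 420 ERCC control spots, against 5% to 10% on the other ret mutant arrays. Wild type arrays detected 0.476% to 20.7% of theirs. Of the negative control spots of ret mutant replicate 1, 0.649% were detected. Ret mutant replicate 2 had a median correlation across probes of 0.911 with the other arrays, against 0.929 to 0.934. Between genotypes, 39 probes were higher and 13 lower without ret mutant replicate 1, and 44 and 17 without ret mutant replicate 2.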

How the results depend on the processing

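Leaving out sets of arrays and the lower floor were chosen after seeing the data. The 120 probes kept their direction in every fit that tested them, but their number did not hold. From 74 higher and 46 lower, an adjusted p under 0.01 gave 28 and 7, array weights 1486 and 1182, slide as a random block 16 and 6, and the wild type controls of slide 2 only 512 and 654. Without wild type arrays 4 to 6 the counts were 568 and 655, with 120 of 120 kept, and without wild type arrays 1 to 6 650 and 792. The lower probes alone moved to 25 with normexp background correction, 18 with no filter on dim probes and 27 without wild type arrays 1 to 3, where 67 of the 120 were kept. Alternatives not named in this part stayed within 1.5 times. The cause was not tested, except as under other observations.

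Leaving out each array in turn gave 34 to 122 higher and 10 to 131 lower probes. Higher probes moved by over 1.5 times without wild type replicates 5 (113) and 6 (122) and ret mutant replicates 1 (39), 2 (44), 4 (35), 5 (34) and 6 (41). Lower probes did without wild type replicates 2 (30), 3 (25), 4 (103), 5 (131), 6 (123), 7 (29), 8 (22), 10 (28), 13 (28), 14 (23) and 15 (30), and ret mutant replicates 1 (13), 2 (17), 4 (10), 5 (12) and 6 (14).

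Deviations of same-numbered arrays correlated over 0.1 in 4 of 6 pairs, and 2 of 6 ret mutant arrays correlated best with their own number, so the numbers were not taken as pairs. With the replicate block, 44 probes were higher and 12 lower, 8 of them among the 120. Numbers above 6 occur only in wild type, so its only controls are wild type arrays 1 to 6, all on slide 3. The 4 named probes passed in 38 of 39 alternatives each, but naming required 2 of these, each wild type slide alone. Most others drop only 1 array. The exception, the replicate block, gave similar log2 folds (3.74, 3.49, -4.53 and -4.46) but limma adjusted p of 0.074 to 0.0919 (lowest elsewhere 2.13e-06).

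The 159 probes between the wild type slides became 42 with no filter on dim probes, 2 without wild type arrays 1 to 3, 4078 without arrays 4 to 6 and 7 without arrays 1 to 6. The difference in overall signal kept its direction. The mean of all probes per gene and the tests of gene lists were not run. Background limits folds at the floor.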

Other observations

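The tests of slide, of wild type arrays 1 to 3 and 4 to 6, of detection and of labels were chosen after the results that prompted them had been seen; the splits of the samples were planned. A first test of the labels of wild type arrays 4 to 6, on probes chosen for parting the arrays, was replaced because that choice favoured the pattern.

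Few splits gave as many as the 120 probes between genotypes: 3 of 100 splits of the 21 arrays, the real one included. Such a count is thus uncommon among splits, but chance is not excluded. The splits mix the slides, unlike the genotypes, so they cannot tell a difference in genotype from one in slide. The highest other split gave 3402, several times the real count, which points to a structure of the samples. It set wild type arrays 1, 2, 3, 7, 12 and 15 against the rest, but a split with 6 in place of 15 gave 3, and the next highest, 403, held none of arrays 1 to 3. With slide as a random block 22 probes passed, and genotype and slide cannot be told apart because no slide holds both genotypes. A difference in genotype stays open and was not separately tested.

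Between the 2 wild type slides, 2 probes passed without wild type arrays 1 to 3, in place of 159, with fewer arrays compared. Leaving out as many other arrays of the same slide, 4 to 6, gave 4078. Yet of 29 other splits drawn with arrays 1 to 3 on one side, 1 called as many and the median was 0, so keeping them together does not by itself give the calls, and their part cannot be told apart from that of the slide. Of 100 splits of the wild type arrays, the real one included, 2 gave as many as the 159, and the highest other gave 2539. That split is the 1 among the 29, and it held the arrays of slide 3 with array 8 in place of array 4. It is thus close to the split by slide and not an unrelated grouping. The second highest of the 29 gave 47. A count of 159 is thus uncommon among splits, but chance is not excluded. Of 410 probes whose 21 values were parted by a gap of at least 2 on the log2 scale with at least 3 arrays on each side, 174 (42.4%) set these 3 arrays against the other 18, and 396 parted arrays within slide 3. Only 28 of the 174 were low on the 3 arrays, which argues against lower detection. Arrays 1, 2 and 3 had 64.3%, 69.5% and 74.7% of probes well above background, against a mean of 64.4% over all wild type arrays. What sets them apart, such as a collection or a genetic background, is not given in the labels and stays open, and no biological explanation was tested.

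Leaving out wild type arrays 4 to 6 raised the count between genotypes to 1223. Of 100 sets of 3 wild type arrays, this one included, 1 gave as many; the highest other, 771, left out replicates 1, 5 and 6, and the median was 75. At the 1223 probes, chosen without these arrays, they lay nearer the ret mutant mean at 72.4%, 84.5% and 87.2% of probes, a mean of 81.4%. Placed 1 at a time, they lay nearer the ret mutant mean at 56.1%, 61.5% and 60.4% of the probes called without them. The other 12 wild type arrays, placed likewise, did so at 3.9% to 19% of probes, and the ret mutant arrays at 51.9% to 91.3%, the lowest being ret mutant replicate 3. Left out together, wild type arrays 1 to 3 did so at 29.9%, 36.1% and 40.2% of 97 probes. A candidate explanation is that these arrays are mislabelled, but this cannot be told apart from wild type neurons that share a background or handling with the mutants. At the named probes, in contrast, arrays 4 to 6 lay on the wild type side of every ret mutant array. For fv00648 they were at the floor, -4.482, and the lowest ret mutant array was at -2.216. For fu04607 they were at 1.645, 2.298 and 2.346, and the highest ret mutant array was at 0.797. The named probes were chosen with these arrays counted as wild type, so they cannot settle the labels. Across probes, arrays 4, 5 and 6 had a median correlation of 0.938, 0.942 and 0.941 with the ret mutant arrays and of 0.913, 0.883 and 0.879 with the wild type arrays. Of the probes parted by a gap, 11 set these arrays and the 6 ret mutant arrays against the other 12 wild type arrays, 21 set them alone against the rest, and 0 set the ret mutant arrays against all 15 wild type arrays. In the replaced test, 36 such probes parted the ret mutant arrays from wild type arrays 7 to 15; arrays 4 to 6 all lay with the ret mutant arrays at 31 of them and with wild type at 2, on probes chosen for the pattern. The level of the mutated gene, which bears on the labels, was not analysed here.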
